A study of Mus musculus with 12 samples.

How the data were processed

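RNA was measured in 12 libraries of mouse mammary epithelial cells, sorted by fluorescence-activated cell sorting from adult females aged 9 weeks on a mixed background of 129X1/SvJ, C57BL/6 and Swiss Webster. Total RNA was isolated with a miRNeasy kit and sequenced on the Illumina platform, per the labels. The 12 libraries form 3 groups of 4. The labels do not say from which animals each library came, so every p value measures the spread between these libraries.

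Per the submitters' processing notes, the authors used STAR, HTSeq 0.3.1 and the mouse build mm9. The notes give no options, strand setting or annotation. The deposited table holds raw read counts, per the file headers and the values, which are whole numbers with a different total in every library. It has 36635 entries with gene symbols, a chromosome and a start position. Of these, 20114 name 1 locus and 16521 name several loci at once. In 3266 of the single-locus entries the name joins several symbols, for example Gli1 with Arhgap9 and Smo with AK053708, so reads of either gene may be in the count. The counts do not show whether strand was used, and a gene and an overlapping or antisense partner cannot be told apart.

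Single-locus entries were analysed. Entries that name several loci held between 0.0617% and 0.101% of the counts of a library and were kept out of the main tests, since their meaning is not stated. Total counts per library lay between 19581993 and 34779433. Loci with enough counts by the default filter of edgeR numbered 14039. The median standard error of a log2 fold change over these loci was 0.37 in recombined against wild type libraries.

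Counts were scaled with the trimmed mean of M values (TMM) and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersion, all 12 libraries in 1 fit and a mean per group. Tests were two-sided, and p values were adjusted by the Benjamini-Hochberg method over the loci tested, with a threshold of 0.05. Values per library are given as CPM, counts relative to library size, with TMM scaling, as mean and SD over 4 libraries. Log2 fold changes have their standard error (SE). Adjusted p values of genes come from this test unless another tool is named.

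Before the data were examined, 33 gene lists of pathways, gland functions and cell types were fixed from textbook knowledge, with 850 entries, of which 839 were found. The 31 lists with at least 5 tested genes were compared with camera of limma 3.58.1 on log2 CPM with a prior count of 2, with the preset correlation between genes of 0.01, and adjusted over the lists of a comparison. Camera with the correlation estimated from the data and the fry test were alternatives. For each list, member genes past the threshold were counted over all loci and also adjusted over the list alone.

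The genes named for each comparison follow a rule written before the data were examined. Smo, Gli1, Ptch1, Hhip and Gnai2 are always named. The 8 genes with the largest rise and the 8 with the largest fall are named among those past the threshold, with a mean log2 CPM of at least 2, no overlap between the libraries of the groups and a descriptive symbol. Up to 4 members are named of each of at most 8 lists past the threshold. Where no gene passed, the 4 with the smallest p are named. A few genes that the rule picks are left out of this text. Genes outside the rule are marked as chosen after their values were seen.

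The replicate numbers were tested as pairs by correlating the deviations of libraries from their group means across loci. Recombined and unrecombined libraries with the same number correlated with r of 0.239, 0.399, 0.244 and 0.298, and pairs of different numbers lay between -0.24 and -0.0345, so the numbers pair these groups. Their library numbers in the labels are adjacent. Wild type libraries of numbers 1 to 4 correlated with r of -0.0314, 0.185, 0.109 and 0.125 with recombined libraries (different numbers -0.147 to 0.169). With unrecombined libraries r was 0.00248, 0.312, 0.157 and 0.159 (different numbers -0.247 to 0.337). They were not taken as paired, since number 1 did not correlate in either. The replicate number was fitted as a block in an alternative.

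Alternatives fixed before the data were examined were other scalings (DESeq2 size factors, upper quartile), the Wald test of DESeq2 1.42.0, limma-voom with and without library weights, no filter and a stricter filter on low counts, only the groups compared, the replicate number as a block, the library number series as a covariate, and each library left out in turn. Alternatives chosen after seeing the data were only the 7 libraries without salivary gland transcripts, the level of those transcripts as a covariate, recombined libraries 3 and 4 left out together, and the lists with the replicate block.

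The fit was tested on simulated data drawn from the real means and library sizes. For recombined against wild type libraries it found 11 of 100 genes changed 2-fold and 57 of 100 changed 4-fold, with 5 false calls. For unrecombined against wild type it found 11 and 57 of 100, with 4 false calls. For recombined against unrecombined it found 13 and 56 of 100, with 2 false calls. The simulation was repeated with all library sizes scaled by 0.25 and 4, a test chosen after seeing the data. In the simulated data of each comparison, camera found the shifted list of 25 genes and called 0 of the 30 unshifted lists. The simulated genes were drawn independently and the unshifted lists at random. This therefore does not test camera on lists whose genes vary together, as those of a cell type may.

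The wild type libraries serve 2 comparisons. Unchanged groups were therefore simulated against the same wild type libraries 20 times, and the wild type libraries were split in all 6 ways. Figures were drawn with matplotlib 3.10.9.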

Results

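RNA of sorted mouse mammary epithelial cells was sequenced in 3 groups of 4 libraries. SmoM2 is an activated form of Smoothened (Smo), the membrane protein that passes on the Hedgehog signal. In this model Cre recombinase, driven by the MMTV promoter, turns on SmoM2 and switches the mT-mG reporter from a red to a green membrane protein. Recombined cells were green and SmoM2 positive. Unrecombined cells had the same genotype and stayed red, without SmoM2. Wild type cells carried the mT-mG and SmoM2 alleles but no Cre. Total counts of recombined libraries 1 to 4 were 32607730, 30250350, 19581993 and 23759927. Those of unrecombined libraries 1 to 4 were 26115857, 34779433, 26341153 and 26818083, and those of wild type libraries 26979461, 26957625, 21603825 and 26467694. Loci of the mitochondrial genome took between 13.1% and 27.8% of the counts.

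The comparison of recombined with wild type cells sets green SmoM2-positive cells against red cells of animals without Cre. SmoM2, Cre activity and the sorted color differ together here, and the kinds of cell may differ too. No group of green cells lacks SmoM2, so these cannot be told apart as the source of any change below. Smo, on mm9 chromosome 6 from position 29685496, had 28.3 ± 7.05 CPM (SD, n = 4) in wild type, 30.4 ± 4.41 in unrecombined and 58.1 ± 11.5 in recombined libraries. It was higher in recombined than in wild type cells by a log2 fold change of 1.04 ± 0.217 (SE), with an adjusted p of 0.0115. The labels do not say which part of the SmoM2 transcript maps to mouse Smo, so this value alone may not check the groups. The canonical Hedgehog targets rose more strongly. Ptch1, the receptor that restrains Smo (chromosome 13, 63609643), went from 36.3 ± 1.54 CPM in wild type to 434 ± 284 in recombined libraries, a log2 change of 3.58 ± 0.443 (adjusted p = 0.000427). Hhip, a Hedgehog ligand binding protein (chromosome 8, 82489749), rose by 3.66 ± 0.533 (adjusted p = 0.0012). The locus of the transcription factor Gli1, counted with Arhgap9 (chromosome 10, 126759171), rose by 2.57 ± 0.450 (adjusted p = 0.00398). For these 4 loci, all 4 recombined libraries lay above all 4 wild type libraries. Gnai2, which encodes the G protein subunit in the title of the series (chromosome 9, 107516468), had 187 ± 57.1 CPM in wild type and 207 ± 33.0 in recombined libraries, a log2 difference of 0.15 ± 0.232 that did not pass (adjusted p = 0.776).

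**Figure D1:**
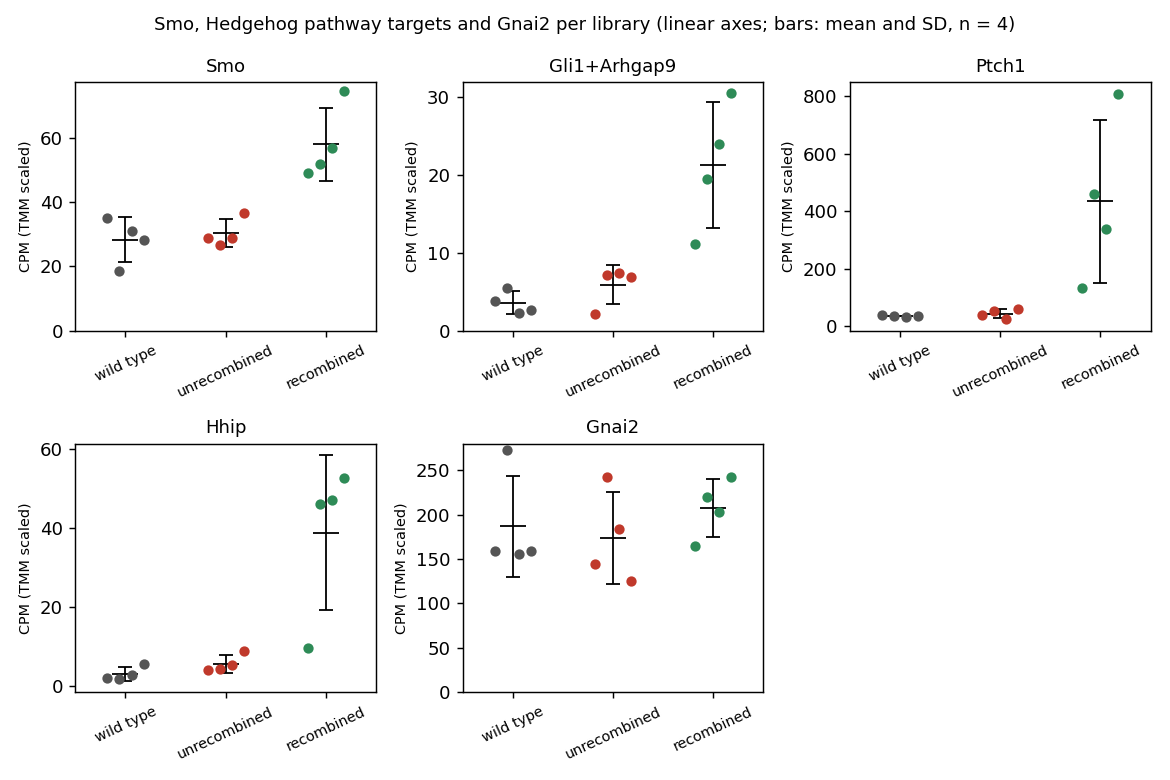
CPM with TMM scaling (vertical axes, linear) of Smo, Gli1 with Arhgap9, Ptch1, Hhip and Gnai2 in each library of the 3 groups, with points for libraries and bars for the mean and SD (n = 4). Recombined libraries averaged 434 CPM of Ptch1 against 36.3 in wild type and 44.8 in unrecombined libraries, whereas Gnai2 averaged 207, 187 and 174.

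Of 18 measured Hedgehog target genes, 8 rose, 1 fell and 9 did not pass in recombined against wild type cells, or 11 and 4 adjusted over the list alone. The target Prdm1, a transcriptional repressor, rose by 3.29 ± 0.365 on the log2 scale. The member that fell was Cdon, a Hedgehog co-receptor, by -0.81 ± 0.205 (adjusted p = 0.0289), a gene named after its values were seen whose call was lost without recombined 2 or 3 or wild type 2, 3 or 4 (adjusted p 0.0581 to 0.106) or with only the 2 groups (0.0556). The list passed camera with an adjusted p of 5.3e-05, and had an adjusted p of 0.136 with an estimated correlation. No list of this comparison passed with an estimated correlation. With fry 10 lists passed, the Hedgehog target list among them (adjusted p = 0.00473). Recombined libraries 3 and 4 lay apart from all others on the first principal component, which held 31.4% of the variance, and had counts in fewer loci (14256 and 14601). Without them Smo (log2 0.83, adjusted p = 0.137) and Gli1 (2.10, adjusted p = 0.0592) did not pass.

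Basal and luminal hormone-sensing markers also separated recombined from wild type cells. Of 24 measured basal and myoepithelial markers, 17 rose and none fell, or 21 and 0 adjusted over the list alone, with a median log2 change of 2.04. Trp63, the transcription factor of basal epithelium, rose from 36.1 ± 13.4 to 344 ± 132 CPM, by 3.25 ± 0.476. The Wnt inhibitor Wif1 rose by 5.49 ± 0.618, the stem cell marker Lgr6 by 1.91 ± 0.305 and Apoe, a lipid carrier, by 1.90 ± 0.275. The list passed with an adjusted p of 6.98e-16, or 0.136 with an estimated correlation. Of 23 luminal hormone-sensing genes, 8 fell and none rose, or 12 and 0 adjusted over the list alone, with a median of -1.44. The prolactin receptor Prlr fell from 3765 ± 1130 to 916 ± 391 CPM, by -2.04 ± 0.310, and the estrogen receptor Esr1 by -1.60 ± 0.264. Ly6a (log2 -2.17) and Cited1 (log2 -1.44) were lower too, and the Cited1 call was lost without recombined 4 or wild type 4 (adjusted p 0.0523 and 0.0786). The adjusted p of this list was 1.84e-08, or 0.136 with an estimated correlation. The Cited1 call was also lost with only the 2 groups (0.0513). Luminal progenitor genes (0 of 21, median 0.31, list adjusted p = 0.327) and milk secretion genes (1 of 22 lower, median 0.55, 0.91) did not pass as lists.

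Fibroblast genes were low in recombined cells. Of 25 measured members, 18 fell and 1 rose, or 20 and 1 adjusted over the list alone, with a median log2 change of -2.17. The collagens Col3a1 (587 ± 286 CPM in wild type and 19.8 ± 7.42 in recombined libraries) and Col1a1 fell by -4.89 ± 0.374 and -4.64 ± 0.447. Pdgfra, a growth factor receptor of fibroblasts, fell by -3.51 ± 0.366, and Mfap5, a microfibril protein, by -5.63 ± 0.508. The member that rose was the matrix protein Fbln2, by 2.73 ± 0.318, named after its values were seen. The list passed with an adjusted p of 1.43e-16, or 0.136 with an estimated correlation. Of 16 macrophage and dendritic cell genes, 4 fell and none rose, or 6 and 0 adjusted over the list alone (list adjusted p = 0.000166, or 0.136 with an estimated correlation). These were Ptprc (log2 -2.54), H2-Aa (-3.19), Cd74 (-2.44) and H2-Ab1 (-2.29). Cd74 lost its call without wild type 4 (adjusted p = 0.068). H2-Ab1 lost it without any of 10 libraries (adjusted p 0.0528 to 0.161), all but unrecombined 2 and 4. With limma-voom H2-Aa (0.0663) and H2-Ab1 (0.0555) did not pass, and with its library weights neither they (0.131 and 0.116) nor Cd74 (0.0764) did. H2-Ab1 was also lost with only the 2 groups (0.0663) or the series covariate (0.0602). Without recombined 3 and 4 none of the 4 passed (0.0915 to 0.185). In edgeR none of 23 endothelial genes passed singly, and 0 passed adjusted over the list alone, while the list had a median of -0.65 and passed with an adjusted p of 0.00019, or 0.26 with an estimated correlation. Its members nearest the threshold were Pecam1 (-1.17, adjusted p = 0.0519), Kdr (-2.01, 0.06), Robo4 (-1.21, 0.251) and Tek (-0.86, 0.277). Without recombined 1 the first 2 and Tek passed (adjusted p 0.00815, 0.0113 and 0.00901), and Pecam1 also without wild type 1 (0.0207). With DESeq2 Pecam1 (0.00887) and Kdr (0.00541) passed. Pecam1 also did with either other scaling or either other filter (0.0383 to 0.0495), and Kdr with the stricter filter (0.0499) or the series covariate (0.0309).

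**Figure D2:**
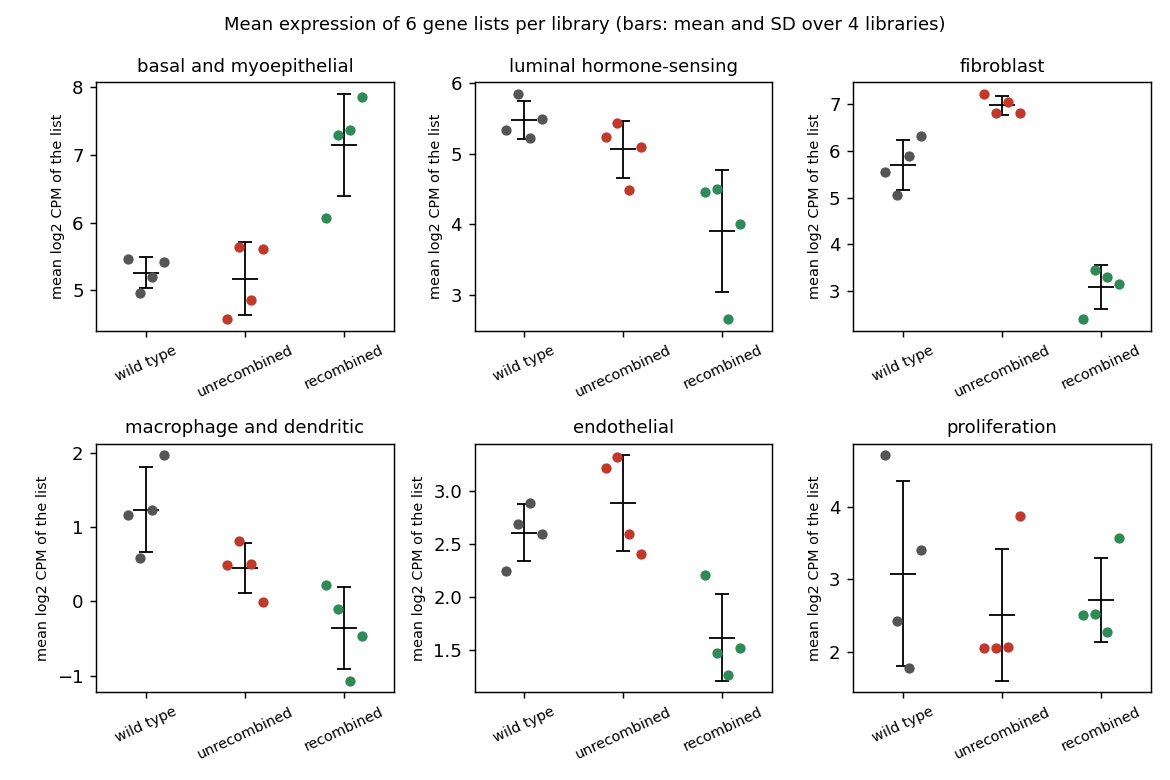
Mean log2 CPM over the tested genes of 6 lists (vertical axes) in each library of the 3 groups, with points for libraries and bars for the mean and SD (n = 4). The fibroblast list averaged 3.07 in recombined, 5.70 in wild type and 6.98 in unrecombined libraries, and the basal list 7.15, 5.26 and 5.17.

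Of 19 Wnt target genes, 8 rose and 1 fell, or 14 and 1 adjusted over the list alone, with a median of 1.38 (list adjusted p = 1.97e-06, or 0.136 with an estimated correlation). Besides Wif1 and Lgr6, Dkk3 rose by 1.50 ± 0.305 and Nkd2, a Wnt antagonist, by 2.20 ± 0.447. The member that fell was Dkk2, an extracellular Wnt modulator, by -3.75 ± 0.833, named after its values were seen, and did not pass with limma-voom (adjusted p = 0.0979), its library weights (0.189) or only the 2 groups (0.0758). Of 28 interferon response genes, 1 fell and none rose, or 10 and 0 adjusted over the list alone (median -0.57, list adjusted p = 9.68e-07, or 0.136 with an estimated correlation). That gene was Gbp2, an interferon-induced GTPase, at -1.19 ± 0.266 (adjusted p = 0.0161), lost without wild type 4 (adjusted p = 0.0548) or with library weights (0.0653). Xaf1 (-1.93, adjusted p = 0.0663) and Oas2 (-2.22, 0.0786) did not pass, although Xaf1 did without recombined 1 (0.0188) and Oas2 without wild type 4 (0.0477). Both passed with DESeq2 (0.0071 and 0.0158). Xaf1 also did with limma-voom (0.0222), its library weights (0.0358) and the series covariate (0.0436). None of 46 proliferation genes passed, and 0 passed adjusted over the list alone, with a median of -0.45 (list adjusted p = 0.393). The cycling marker Mki67, named after its values were seen, had 181 ± 225 CPM in wild type and 51.9 ± 43.5 in recombined libraries, a log2 difference of -1.81 ± 1.20 (adjusted p = 0.454).

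Across all loci, 586 rose and 334 fell in recombined against wild type cells, 920 of 14039 tested, with 458 and 274 of them by more than 2-fold. Besides Wif1, the largest rises by the naming rule were the desmosomal cadherin Dsc3 (log2 5.08 ± 1.19), Ppp1r14c (4.52 ± 0.554, chromosome 10, 6881565), the collagen Col27a1 (4.48 ± 0.465), Aff3 (4.37 ± 0.637), the sodium leak channel Nalcn (4.22 ± 0.620), Chst11 (4.00 ± 0.592) and Egfl6 (3.70 ± 0.873). Besides Mfap5, the largest falls were the matrix proteoglycan Podn (-5.73 ± 0.650), Scg3 (-5.44 ± 0.889), Clec3b (-5.37 ± 0.885), the matrix protein Thbs2 (-5.29 ± 0.522), Abca8a (-5.16 ± 0.491), Pla1a (-5.04 ± 0.826) and the laminin chain Lama2 (-4.91 ± 0.780). The call of Dsc3 was lost without recombined 3 or 4 or any wild type library (adjusted p 0.0602 to 0.0997), with log2 changes of 4.81 to 5.46. That of Egfl6 was lost without recombined 3 or wild type 1, 3 or 4 (0.0544 to 0.0662), with 3.30 to 3.98. Dsc3, Scg3 and Clec3b did not pass with limma-voom (adjusted p 0.101, 0.076 and 0.0665) or its library weights (0.0978, 0.138 and 0.115), nor did Dsc3 without the filter (0.064) or with the series covariate (0.055). Of 31 lists 12 passed, 6 higher and 6 lower, and the 8 named above kept their calls without any single library. Matrix (13 of 30 higher and 6 lower, adjusted p = 0.0219, or 0.653 with an estimated correlation), Notch, Hedgehog component and oxidative phosphorylation genes passed with adjusted p of 0.0219 to 0.0497 and lost their calls without single libraries. The total fell to 612, 600 and 502 without wild type 2, 3 and 4 and to 248 (128 higher and 120 lower) without recombined 3 and 4, and was 1617 with DESeq2.

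The comparison of unrecombined with wild type cells asks whether SmoM2-negative cells of the recombined genotype differ from cells of animals without Cre. The unrecombined libraries lack the cells that had turned green, while no cell was turned green in wild type. The kinds of cell may therefore differ here too. Fibroblast and matrix genes had higher values in unrecombined libraries, although no single gene passed in edgeR. All 25 fibroblast markers were higher, with a median log2 difference of 1.21, and 16 passed adjusted over the list alone. Postn, a matrix protein, had 864 ± 148 CPM in wild type and 2070 ± 365 in unrecombined libraries (1.26 ± 0.226, adjusted p = 0.128). Col3a1 (1.58 ± 0.325, adjusted p = 0.215), Col6a2 (1.20 ± 0.215, 0.128) and Pdgfra (1.60 ± 0.338, 0.233) were also higher in all 4 unrecombined libraries than in any wild type library. The list passed with an adjusted p of 3.14e-28, or 0.0656 with an estimated correlation. The matrix list had a median of 0.50 (adjusted p = 1.41e-08, or 0.305 with an estimated correlation), with 7 of 30 members passing adjusted over the list alone. Its leading members were the basement membrane protein Nid1 (1.31 ± 0.227, adjusted p = 0.128), Sparc (1.14, 0.46), the metalloproteinase Mmp3 (2.15, 0.512) and Adamts5 (1.07, 0.537). DESeq2 called Postn (0.000515), Col6a2 (0.00029), Col3a1 (0.00156), Pdgfra (0.0019), Nid1 (0.00029), Mmp3 (0.0234) and Sparc (0.0402). Limma-voom called the first 6 of these (each 0.0287), as did its library weights (0.00537 to 0.0114). Macrophage and dendritic genes had a median of -0.81 (list adjusted p = 3.67e-05, or 0.305 with an estimated correlation), 0 of 16 passing adjusted over the list alone, with Cd74 at -1.66, Ptprc at -1.45, H2-Aa at -1.40 and H2-Ab1 at -1.27.

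Smo differed by 0.10 ± 0.215 on the log2 scale between unrecombined and wild type cells. The differences were 0.73 ± 0.431 for Gli1, 0.30 ± 0.402 for Ptch1, 0.88 ± 0.491 for Hhip and -0.10 ± 0.232 for Gnai2, each with an adjusted p of 1. The Hedgehog target list had a median of 0.40 and passed with an adjusted p of 0.00172, or 0.425 with an estimated correlation, with 0 of 18 members passing adjusted over the list alone. Its leading members were Sfrp1 (1.07), Prdm1 (0.89), Ccnd2 (0.97) and Hsd11b1 (1.70), and the list call was lost without unrecombined 4 (adjusted p = 0.0586). Proliferation genes had a median of -0.78 (list adjusted p = 0.000144, or 0.642 with an estimated correlation), 0 of 46 passing adjusted over the list alone. That call was lost without wild type 1 (adjusted p = 0.719), and Ccnb2 (-1.52), Gins2 counted with Gse1 (-0.50), Mcm4 (-0.67) and Mcm6 (-0.90) had the smallest p. The epithelial-mesenchymal transition list (median 0.46, adjusted p = 0.000521, or 0.425 with an estimated correlation, 3 higher and 1 lower of 21 adjusted over the list alone) was led by Fn1 (1.47), Mmp2 (1.46) and Vim (0.72). Luminal hormone-sensing genes (median -0.35, adjusted p = 0.00172, or 0.538 with an estimated correlation, 0 of 23 adjusted over the list alone) included Stat5a (-0.51), Esr1 (-0.53), Ly6a (-0.75) and Tbx3 (-0.39), and this call was lost without wild type 2 (adjusted p = 0.0529). Luminal progenitor genes (median 0.36, adjusted p = 0.00279, or 0.538 with an estimated correlation, 1 of 21 adjusted over the list alone) included Spp1 (1.84), Trf (1.02), Mfge8 (0.58) and Plb1 (1.05).

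In edgeR, 0 of 14039 loci passed in unrecombined against wild type cells. Of these, 541 had an unadjusted p under 0.05, or 3.85%, and the smallest adjusted p was 0.128. The 4 loci with the smallest p were Itm2a (1.61 ± 0.248), Spon1 (1.61 ± 0.265), the matrix protein tenascin N, Tnn (15.9 ± 3.69 CPM in wild type and 3.97 ± 0.595 in unrecombined libraries), and Nid1. Of 31 lists 15 passed, 10 higher and 5 lower, without a member past the threshold, and with fry only the fibroblast list did (adjusted p = 0.0371). No list passed camera with an estimated correlation (smallest adjusted p = 0.0656). DESeq2 called 78 loci, limma-voom 25 and limma-voom with library weights 74. Itm2a (adjusted p 6.74e-07 and 0.0186), Spon1 and Tnn (3.53e-05 and 0.0287 each) passed with DESeq2 and with limma-voom. Fn1 (0.0368) and Spp1 (0.00519) also passed with DESeq2, and Fn1 (0.0146) and Sfrp1 (0.0474) with the library weights. With only the groups compared edgeR called 8, among them Itm2a (0.0453), Tnn (0.0446) and Postn (0.0453).

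The comparison of recombined with unrecombined cells sets SmoM2-positive against SmoM2-negative cells of the same genotype. The sorted color differs with SmoM2 here as well, and the kinds of cell may differ too. Smo was higher by 0.93 ± 0.217 on the log2 scale (adjusted p = 0.0208). Ptch1 rose by 3.28 ± 0.437 from 44.8 ± 15.7 CPM (adjusted p = 0.000528), Hhip by 2.78 ± 0.511 from 5.66 ± 2.26 CPM (0.00496) and Gli1 by 1.85 ± 0.437 from 5.91 ± 2.53 CPM (0.0234). Gnai2 differed by 0.26 ± 0.232 (adjusted p = 0.624). Smo lost its call without recombined 4 or unrecombined 1, 2 or 3 (adjusted p 0.0615 to 0.0715), and Gli1 without recombined 3 or 4 or unrecombined 1, 2 or 4 (0.0503 to 0.0715). These fits did not use the pairing by replicate number. With the replicate block in the 2 groups, all 4 of Smo, Gli1, Ptch1 and Hhip passed. Without recombined 3 and 4 together, only Ptch1 of the 4 passed. Smo also lost its call in only the 7 libraries without salivary transcripts (log2 1.02, adjusted p = 0.0763). Of 18 Hedgehog targets 7 rose, among them Prdm1 (2.41 ± 0.351) and Fst (2.31 ± 0.383), an activin inhibitor. The steroid enzyme gene Hsd11b1 fell, at -4.11 ± 0.947, named after its values were seen, and lost its call without recombined 4 or unrecombined 1 (adjusted p 0.0787 and 0.0594) or the filter (0.0598). Adjusted over the list alone, 7 rose and 4 fell. The list passed with an adjusted p of 0.0101, or 0.4 with an estimated correlation, and not without recombined 4 (adjusted p = 0.0548).

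The fibroblast list differed most. Of 25 members 21 fell and 1 (Fbln2) rose, or 23 and 1 adjusted over the list alone, with a median log2 change of -3.44 (list adjusted p = 8.66e-30, or 0.0552 with an estimated correlation). Col3a1 fell from 1752 ± 432 CPM, by -6.47 ± 0.403, Col6a2 by -3.14 ± 0.232, Mfap5 by -6.98 ± 0.532 and Pdgfra by -5.12 ± 0.394. Of 24 basal and myoepithelial markers 19 rose and 1 (Vim, an intermediate filament of many mesenchymal cells) fell, or 20 and 1 adjusted over the list alone, with a median of 2.40 (list adjusted p = 2.92e-16, or 0.233 with an estimated correlation). Vim, named after its values were seen, lost its call without recombined 2 or 3 or unrecombined 1 or 3 (adjusted p 0.0564 to 0.107). Krt14, a basal keratin, rose by 3.12 ± 0.464 and Krt5 by 3.38 ± 0.636. Col17a1, a hemidesmosome protein, rose by 3.07 ± 0.408, Trp63 by 3.30 ± 0.477 and Myh11, a smooth muscle myosin, by 2.48 ± 0.373. Of 23 luminal hormone-sensing genes 4 fell, or 10 adjusted over the list alone, with a median of -1.13 (list adjusted p = 1.97e-05, or 0.298 with an estimated correlation). Prlr fell by -1.60 ± 0.305. Esr1 (-1.08), Cited1 (-1.33) and Prom1 (-1.49) passed with adjusted p of 0.0266, 0.0345 and 0.0461. Esr1 lost its call without any of recombined 2 and 3 and unrecombined 1, 3 and 4 (0.0543 to 0.0791). Cited1 lost it without recombined 2 or 4 or unrecombined 1, 2 or 4 (0.0637 to 0.0930), and Prom1 without any of 8 libraries (0.0666 to 0.139), all but recombined 2, unrecombined 1 and wild type 1 and 2. Cited1 also lost it with only the 2 groups (0.0707), and Prom1 without the filter (0.0744), with limma-voom (0.0673) and with its library weights (0.293).

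Of 19 Wnt targets 5 rose and 1 (Dkk2) fell, or 12 and 1 adjusted over the list alone, with a median of 1.18 (list adjusted p = 0.000186, or 0.305 with an estimated correlation). Wif1 rose by 3.59 ± 0.563, Lgr6 by 1.74 ± 0.303, Nkd1 by 2.26 ± 0.490 and Lgr5 by 2.12 ± 0.495. Nkd1 lost its call without unrecombined 1 or 3 (adjusted p 0.0519 and 0.0509) and Lgr5 without recombined 3 or 4 or unrecombined 2 (0.0617 to 0.0717). With limma-voom Nkd1 (0.0817), with its library weights Dkk2 (0.053) and with only the 2 groups Lgr5 (0.0607) did not pass. Of 29 genes that respond to tissue dissociation 4 rose, also 4 adjusted over the list alone, with a median of 0.11 (list adjusted p = 0.0324, or 0.681 with an estimated correlation). These were the immediate early genes Egr2 (1.35) and Egr3 (1.65), Socs3 (1.67) and Ctgf, counted with AK014660 (1.72). Egr3 lost its call without recombined 3 (adjusted p = 0.0534) or with library weights (0.0525), and the list lost it without recombined 4 or unrecombined 4 (0.127 and 0.0553). Of 23 endothelial genes Kdr, a receptor of vascular growth factor, fell by -2.43 ± 0.603, and 4 passed adjusted over the list alone (median -1.09, list adjusted p = 2.12e-06, or 0.233 with an estimated correlation). The Kdr call was lost without recombined 2 or 4 or unrecombined 1 or 2 (0.0563 to 0.0994) or with only the 2 groups (0.0852). Of 28 interferon response genes Gbp2 fell (-1.03 ± 0.266), also 1 adjusted over the list alone (median -0.91, list adjusted p = 1.59e-05, or 0.233 with an estimated correlation), a call lost without any of 8 libraries (0.0551 to 0.136), all but recombined 1, unrecombined 4 and wild type 1 and 2. Gbp2 was also lost with limma-voom (0.0517), its library weights (0.0913) and only the 2 groups (0.0915). Flt1 (-1.29, adjusted p = 0.0534), Pecam1 (-1.20, 0.0551), Emcn (-1.42, 0.0724) and Oasl2 (-1.28, 0.0664) did not pass, and each passed with the replicate block in a fit of the 2 groups (0.0196, 0.0115, 0.0416 and 0.0173). Mx2 (-1.60, 0.0935) and Xaf1 (-1.83, 0.094) did not pass. Single left-out libraries brought in Flt1, Pecam1, Emcn and Xaf1 (recombined 1, adjusted p 0.0349, 0.00766, 0.0257 and 0.0258), Pecam1 again (wild type 1, 0.0315), Emcn again (wild type 2, 0.0414) and Mx2 (recombined 4, 0.0412). With DESeq2 all 6 passed (Flt1 0.00692, Pecam1 0.00815, Emcn 0.0127, Oasl2 0.0106, Mx2 0.0211 and Xaf1 0.0139), and Xaf1 did with limma-voom (0.0251) and its library weights (0.0386). With the series covariate Flt1 (0.0229), Pecam1 (0.0434) and Xaf1 (0.0387) passed, with the stricter filter Flt1 (0.0445) and Pecam1 (0.0429), and without the filter Pecam1 (0.0469). The block over all 12 libraries brought in Flt1 (0.0267) and Oasl2 (0.0467). None of 46 proliferation genes passed, and 0 adjusted over the list alone (median 0.18, list adjusted p = 0.271).

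Across all loci, 433 rose and 300 fell in recombined against unrecombined cells, 733 of 14039. Besides Wif1, Krt5 and Trp63, the largest rises were the teneurin Odz2, also called ten-m2 (3.70 ± 0.402), Egfl6 (3.58 ± 0.868), the metalloproteinase Adamts18 (3.54 ± 0.526), the ephrin receptor Ephb1 (3.42 ± 0.521) and Nalcn (3.40 ± 0.595). Besides Mfap5 and Col3a1, the largest falls were Pla1a (-6.91 ± 0.884), Thbs2 (-6.89 ± 0.555), Abca8a (-6.67 ± 0.524), Mmp3 (-6.62 ± 0.712), Lama2 (-6.51 ± 0.837) and Podn (-6.36 ± 0.665). Egfl6 lost its call without recombined 3 or 4 or unrecombined 1 or 4 (adjusted p 0.0507 to 0.101), without the filter (0.0623) or with the replicate block over all 12 libraries (0.0656). Of 31 lists 9 passed, 5 higher and 4 lower, and no list passed camera with an estimated correlation (smallest adjusted p = 0.0552). With fry 9 lists passed, 8 of them the same. The total fell to 449 without unrecombined 1 and was 1349 with DESeq2. Without recombined 3 and 4 it was 282, and most of these were lower (100 higher and 182 lower).

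The changes against wild type in recombined and in unrecombined cells correlated across loci with r = 0.3001, and genes are not independent replicates. Both use the same wild type libraries, and simulated unchanged groups gave r = 0.0991 (0.0258 to 0.187). The covariance was 0.213 against 0.0255 in the simulation, a difference of 0.188. This difference is not assigned to SmoM2 or genotype, since the replicate numbers also pair recombined with unrecombined libraries, which the simulation leaves out. With the wild type libraries split between the comparisons r was 0.0676, with a covariance of 0.0694, and the pairing remains in this split. The split lowered the covariance by more than the 0.0255 of the simulation. The simulation thus understates what sharing the wild type libraries adds, and the difference of 0.188 overstates the excess. Of the loci higher in recombined than in wild type and those higher than in unrecombined cells, 346 were the same genes, as were 201 lower loci. Independent lists of these sizes would share 18.1 and 7.14. Simulated unchanged groups had 0 loci called against wild type, and so could share only 0. With the recombined libraries split between the comparisons the lists averaged 430 and 353 higher and 299 and 299 lower loci, and 130 and 95.2 were shared.

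Transcripts of salivary glands were present in 5 libraries spread over the 3 groups. A list of 18 loci of such transcripts, written after the data were seen, took 0.142% of the counts in recombined 1 and 1.93% in recombined 2. It took 0.154% in unrecombined 1, 7.46% in unrecombined 2 and 4.18% in wild type 2. The 95% Wilson intervals of these shares were 0.140% to 0.143%, 1.92% to 1.93%, 0.153% to 0.156%, 7.45% to 7.47% and 4.17% to 4.18%, and cover counting error only. In the other 7 libraries the share was at most 0.00923%. Psp, the parotid secretory protein, reached 31030 CPM in unrecombined 2 and was at or under 0.187 CPM in those 7.

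**Figure D3:**
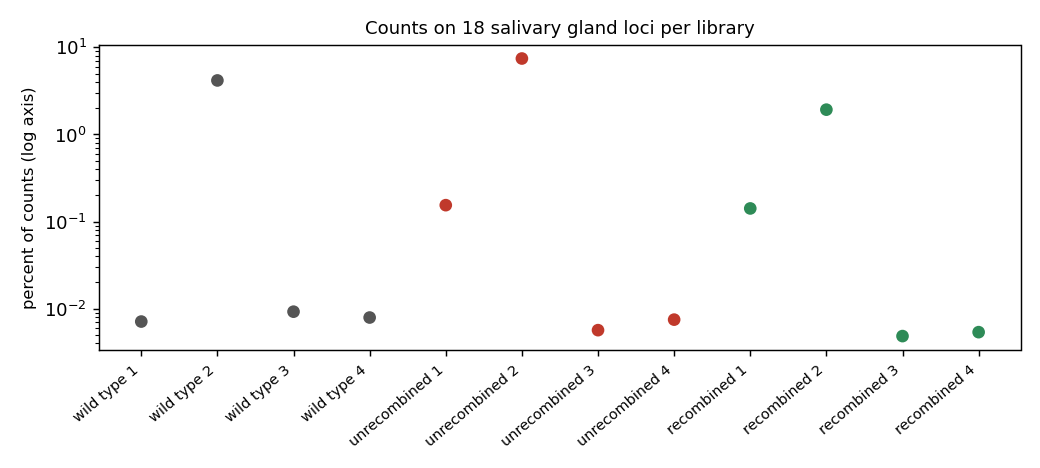
Percent of counts on 18 salivary gland loci (vertical axis, log scale) in each of the 12 libraries, colored by group. Recombined 1 and 2, unrecombined 1 and 2 and wild type 2 lie between 0.142% and 7.46%, and the other 7 at or under 0.00923%.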

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

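All tests reported in this part were chosen after the values were seen, except the rule that marks a library whose gap to the nearest of its group exceeds the 95% critical share of the group's range by Dixon's test. Of 267 gene and group tests 21 met that rule, with 13.4 expected by chance, and of 36 tests of library measures 6 did.

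Salivary gland transcripts took 4.18% of the counts in wild type 2, 7.46% in unrecombined 2 and 1.93% in recombined 2, each far above most of its group, and were also present in recombined 1 and unrecombined 1. All 5 carry library numbers of the lower series, but that series alone is argued against as the source, since another library of it had 0.111 CPM of Psp. So is the group, since 3 of the 3 groups hold libraries with and without these transcripts. A candidate source, at least in unrecombined 2 and recombined 2, is salivary gland tissue in the preparation. For 15 of 15 detected genes of a separate salivary list the highest library was among the 5 (exact binomial p = 1.98e-06, though 11 are Klk1b paralogs and not independent), 2 of them exceeding 1 CPM in another library as well. The highest library was unrecombined 2 for 13 genes and recombined 2 for 2, so this count says nothing about the other 3. In recombined 1, unrecombined 1 and wild type 2, 2, 4 and 7 of the 15 lay above all 7 other libraries. Klk1, Muc19 and Prol1 together had 0, 0.690 and 63.6 CPM in these 3, against 1572 in recombined 2 and 2221 in unrecombined 2, and the source in these 3 stays open. The route into cells sorted for a membrane reporter stays open, and no biological explanation was tested.

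In wild type 2, Gnai2 was higher than in the other libraries of its group (272 CPM against 156 to 159). In the same library 5 genes were lower than in the rest of the group: Col27a1 at 2.28 CPM, Aff3 at 1.08 CPM, Chst11 at 1.36 CPM, Egfl6 at 0.194 CPM and Trp63 at 16.3 CPM.

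Among the other wild type libraries, H2-Ab1 stood out in number 4 at 25.2 CPM, Col6a2 in number 4 at 35.8 CPM and Mcm4 in number 1 at 73.6 CPM. In unrecombined 1, Gli1 with Arhgap9 was low at 2.14 CPM, against 6.86 to 7.44 CPM in the rest of the group. In the same library Lama2 was high at 526 CPM and Col6a2 at 70.2 CPM. In unrecombined 4, Lgr6 reached 27.1 CPM and Ccnb2 8.39 CPM, and the mean log2 CPM of the proliferation list was 3.87 against 2.05 to 2.07 in the other unrecombined libraries. In unrecombined 3, Mx2 was low at 2.23 CPM, and in unrecombined 2, Egr3 was low at 81.5 CPM. In recombined 1, Hhip was low at 9.71 CPM, against 46.2 to 52.6 CPM in the rest of the group, and Pecam1 was high at 34.8 CPM. In recombined 2, Ly6a was high at 57.8 CPM and Tnn at 8.25 CPM, and in recombined 4, Oasl2 was low at 4.29 CPM. Total counts stood apart in wild type 3 at 21603825 and in unrecombined 2 at 34779433.

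Entries that name several loci, which the comparisons do not use, also held a signal. Of 191 such entries with enough counts, 5 were higher and 11 lower in recombined than in wild type cells in edgeR. The smallest p was that of Krt14 joined with Krt17, both basal keratins, with a log2 fold change of 2.60 (adjusted p = 0.00413).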

How the results depend on the processing

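Only the settings with only the 7 libraries without salivary transcripts, the salivary covariate, recombined 3 and 4 left out together, the lists with a replicate block and the simulated depths were chosen after seeing the data. Where a value differs, the cause was not tested. With fewer libraries, lost power cannot be told apart from an effect of the libraries left out. For recombined against wild type (920 loci), DESeq2 gave 1617, only the 2 groups 594, the replicate block in these groups 609, recombined 3 and 4 left out 248, and leaving out 1 library 502 to 1217. For unrecombined against wild type (0), DESeq2 gave 78, limma-voom 25, its library weights 74, only the 2 groups 8, the replicate block 18 in these groups and 1 with all 12 libraries, and leaving out 1 library 0 to 0. For recombined against unrecombined (733), DESeq2 gave 1349, recombined 3 and 4 left out 282 (100 higher and 182 lower, against 433 and 300), and leaving out 1 library 449 to 1044. The replicate block in these 2 groups gave 984 loci, 621 of them the same genes, and besides the 4 gene calls given with the results and an oxidative phosphorylation list call (adjusted p = 0.0215) it changed no call of a named gene or list. In recombined against wild type, which the numbers do not pair, the block over all 12 libraries brought in Pecam1 (0.0494), Kdr (0.0272), Xaf1 (0.0407), Krt8 (0.0307) and Krt18 (0.0344). It took out Dsc3 (0.058), Egfl6 (0.0511) and Wnt2 (0.0652). In the 2 groups alone the block took out Ptprc (0.0541), Cd74 (0.0656), Nkd2 (0.0728), Cdon (0.0638), Dkk2 (0.0672), Hes1 (0.0852) and Snai2 (0.0533). In unrecombined against wild type it brought in Itm2a, Tnn, Mmp3, Fn1 and Sfrp1 (0.0456 each) and Postn (0.041). Only the 7 libraries gave 997, 0 and 568 loci in the 3 comparisons, and the salivary covariate 1224, 0 and 798. Of the 997 and 568 loci, 592 and 401 also passed in the main fit. The only recombined libraries among the 7 are 3 and 4, which also lay apart on the first principal component. For recombined cells, salivary transcripts thus cannot be told apart from whatever else sets these libraries apart.

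Of Smo, Gli1, Ptch1 and Hhip, 4 passed in recombined against wild type without any single library and 2 without recombined 3 and 4. Against unrecombined cells 4 passed, 1 without recombined 3 and 4, 3 in only the 7 libraries (without Smo), and 2 to 4 without 1 library (2 without recombined 4, unrecombined 1 or unrecombined 2). With an estimated correlation 0 lists passed in each comparison, also with the replicate block in the 2 groups (0). With fry 10 passed for recombined against wild type, 1 for unrecombined against wild type and 9 for recombined against unrecombined. Leaving out 1 library gave 8 to 13, 10 to 16 and 7 to 11 lists. The correlation of changes, 0.3001, lay between 0.226 and 0.443 without 1 library, at 0.234 with the stricter filter and at 0.0676 with the wild type libraries split. In unrecombined against wild type, the adipocyte list turned direction in the 7 libraries (adjusted p = 0.904). Smo turned to -0.00315 without unrecombined 4 and -0.052 without wild type 2, within -0.052 to 0.23 without 1 library. Gnai2 turned to 0.026 and 0.14 in these settings, within -0.30 to 0.14. Of the named gene calls, leaving out 1 library lost 0 to 6 of 38 against wild type and 0 to 8 of 40 against unrecombined cells. Recombined 3 and 4 left out together lost 13 and 16. The median log2 fold change of all loci was at most 0.0834 in size in every comparison and setting. Simulated libraries of 0.25, 1 and 4 times the depth with the dispersion kept found 19, 13 and 10 of 100 2-fold changes in recombined against wild type, 16, 15 and 10 in unrecombined against wild type and 19, 10 and 12 in recombined against unrecombined. Of 100 4-fold changes they found 57, 59 and 59, then 54, 57 and 56, then 57, 55 and 55. Recovery showed no steady rise with depth.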

Other observations

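The genes in the next 2 paragraphs were chosen after their values were seen, from lists fixed before the data were examined. For the genes of these paragraphs, a shift in basal or fibroblast share cannot be told apart from a change within cells. The tests of basal share and of fibroblasts were also chosen after the result was seen, and the counts over other splits of the libraries were planned.

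Single genes of the matrix list moved both ways in recombined against wild type cells. The laminin chains Lama1 (log2 3.39 ± 0.477, adjusted p = 0.00107), Lama3 (2.28 ± 0.317, 0.000875) and Lamb3 (2.31 ± 0.263, 0.000241) rose, whereas Lama2 fell as given in the results and fibronectin, Fn1, fell by -3.92 ± 0.441 (0.000241). The list (13 of 30 higher and 6 lower) had an adjusted p of 0.0219, or 0.246 with fry and 0.653 with an estimated correlation, and lost its call without recombined 3 or 4 or wild type 2 (0.0571 to 0.114). The transcription factors Zeb1 (-2.41 ± 0.391, 0.00243) and Zeb2 (-2.34 ± 0.353, 0.00149) fell and Snai2 rose (2.55 ± 0.467, 0.00519), while the epithelial-mesenchymal transition list as a whole did not pass (4 members higher and 4 lower of 21, or 8 and 4 adjusted over the list alone, list adjusted p = 0.287). The keratins Krt8 (-0.99 ± 0.288, 0.0557) and Krt18 (-0.96 ± 0.297, 0.0712) did not pass, although each did without recombined 1 (0.021 and 0.031) and Krt8 did without wild type 1 (0.0407). Both passed with DESeq2 (0.012 and 0.0194), and Krt8 with the upper quartile scaling (0.0478), the stricter filter (0.044) and limma-voom (0.0487).

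Genes of the Notch and growth factor lists also moved both ways. The Notch ligands Dll1 (2.88 ± 0.298, adjusted p = 0.000127), Jag1 (1.67 ± 0.317, 0.00666) and Jag2 (2.91 ± 0.623, 0.0128) rose in recombined against wild type cells, and by 2.68, 1.72 and 3.10 against unrecombined cells. The Notch target Hes1 fell against wild type (-0.999 ± 0.272, 0.0424), a call lost without any of 10 libraries (0.0504 to 0.112), all but recombined 1 and unrecombined 3. Library weights (0.0722) and only the 2 groups (0.0866) ended it too. The Notch list (3 of 17 higher and 1 lower) had an adjusted p of 0.027, or 0.136 with an estimated correlation. It lost its call without recombined 1, 3 or 4, unrecombined 1, 2 or 4 or wild type 1 or 4 (0.0792 to 0.224). The growth factor list did not pass (4 of 40 higher and 3 lower, or 4 and 5 adjusted over the list alone, list adjusted p = 0.878). Bmp7 (2.93 ± 0.481, 0.00262), Nrg1 (1.82 ± 0.318, 0.00398), Pdgfa (1.75 ± 0.366, 0.0115) and Cxcl12 (1.18 ± 0.323, 0.0436) rose. Igf1 (-3.55 ± 0.722, 0.012) and Areg (-1.86 ± 0.443, 0.0235) fell, as did Wnt2 (0.570 ± 0.584 CPM in wild type and 0 in recombined libraries, 0.0372). Areg lost its call without recombined 1 or 4 or wild type 1 or 2 (0.0507 to 0.0756), without the filter (0.051) and with library weights (0.0715). Cxcl12 lost it without any of 9 libraries (0.051 to 0.127), all but recombined 1 and unrecombined 1 and 2, and with 5 other planned settings (0.0529 to 0.0803). Wnt2 lost it without any of 11, all but wild type 2 (0.0536 to 0.0978), with limma-voom (0.16) and with its library weights (0.117). The Hedgehog transcription factor Gli2 rose by 2.97 ± 0.483 (0.00251), from 1.94 ± 0.688 to 15.3 ± 9.17 CPM. Of the inhibitory G protein subunits, Gnai1 rose from 14.5 ± 4.57 to 64.8 ± 23.9 CPM, by 2.15 ± 0.329 against wild type (0.0016) and by 1.26 ± 0.319 against unrecombined cells (0.0335). Its second call was lost without recombined 2, 3 or 4, unrecombined 1, 3 or 4 or wild type 4 (0.051 to 0.108) or with only the 2 groups (0.0605). Gnai3 differed from wild type by 0.14 ± 0.134 (0.6), and the list of G protein subunits did not pass (1 of 25 higher, or 2 adjusted over the list alone, median -0.02, camera direction higher, adjusted p = 0.878).

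The rise of Hedgehog targets in recombined libraries came with a rise of basal markers. More fibroblasts are argued against as the source, since the fibroblast list had a median change of -2.17 with no overlap between the groups. A larger share of basal cells may account for the rise or for part of it, and cannot be told apart from a change within cells. The mean log2 CPM of Gli1, Ptch1 and Hhip minus that of Krt5, Krt14 and Trp63 was -2.67 ± 0.249 in recombined and -2.75 ± 0.538 in wild type libraries, a difference of 0.082 (exact permutation p = 0.8, two-sided, n = 4). Against the whole basal list the difference from wild type was 1.23 (exact permutation p = 0.0286, the smallest possible with 4 against 4). Against unrecombined libraries, which the replicate numbers pair, the 2 differences were -0.86 and 0.54 (each 0.125 with the signs of the 4 within-pair differences turned, the smallest possible), and decide nothing. For wild type the answer depends on which basal genes are used.

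In unrecombined libraries fibroblast markers were higher than in wild type libraries. A lower share of epithelial cells would raise the other cell types alike, if these kept their proportions. Under that condition the values below argue against it as the whole cause. The mean log2 CPM of the fibroblast list minus that of the macrophage list was 6.53 ± 0.368 in unrecombined and 4.46 ± 0.146 in wild type libraries, a difference of 2.07 (exact permutation p = 0.0286), or 2.22 with the 11 macrophage genes over 1 CPM (0.0286). The macrophage list itself averaged 0.451 ± 0.340 in unrecombined and 1.24 ± 0.571 in wild type libraries, so its lower level makes up part of these differences. It was chosen after these values were seen, so the p values of these tests lend little support. Against pericyte genes the fibroblast difference was 1.05 (0.0286). Against endothelial and adipocyte genes it was 0.99 and 0.72, with overlap (0.0571 each), so a lower share may still add to the rise. A larger share of fibroblasts cannot be told apart from a change within cells, since the 25 of 25 markers that were higher are the pattern itself. Of these markers 1 is also in another list, and 22 had a mean over 1 CPM in recombined libraries too, where the abundant Postn and Col3a1 averaged 329.5 and 19.8 CPM. Expression of these genes in other sorted cells stays open, as does an effect of the genotype. So does the sort itself, which left the green cells out of the unrecombined libraries. The labels do not describe a gate that would remove fibroblasts.

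Other splits of the 8 libraries of each comparison were fitted, 35 in all with the real one. In recombined against wild type cells 1 of 35 gave as many changed loci as the real split (920), and the highest other count was 0. This is the smallest share that 35 splits can give, so chance is argued against but not excluded. Every other split mixes libraries of the 2 groups, and no split can tell SmoM2 from sorted color or cell types. The count for Smo and the 3 Hedgehog targets Gli1, Ptch1 and Hhip behaved alike, with 4 passing, 1 of 35 as large and a highest other count of 0. The replicate numbers pair recombined with unrecombined libraries, and only 8 splits part the 4 pairs, too few for a share under 0.05. Of these 8 splits, 1 gave as many changed loci as the real one (733, highest other 0), 1 as many of the 4 Hedgehog genes (4, highest other 0) and 2 as many lists (9, highest other 17). The other 27 splits of these libraries gave 0 changed loci. In unrecombined against wild type cells the real count of changed loci was 0, which 35 of 35 splits reach by construction (highest other 0), so they say nothing about chance. For the number of lists chance cannot be excluded in recombined against wild type (12, reached by 8 of 35 splits, highest other 14). In unrecombined against wild type cells 2 of 35 splits reached the 15 lists (highest other 15), and chance cannot be excluded there either.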
